A study of Mus musculus with 6 samples.

How the data were processed

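The data were 6 peak lists from ATAC-seq of sorted mouse back skin cells, 1 list per library and 2 libraries for each of touch dome, IFE and HF. Per the labels' protocols, the mice received tamoxifen at 100 µg per g body weight on postnatal days 51 and 52 and were used on day 60. Libraries were made with a commercial ATAC-seq kit from 50000 sorted cells. Per the submitters' processing notes, the tools were Trim Galore 0.6.7, Bowtie2 2.4.5, SAMtools 1.9 and MACS2 2.2.7.1, with the genome build mm10. Their settings, read filters, any shift of reads for the transposase cut and the peak threshold are not given in the sources used here. The deposited lists give the chromosome, start, end and name of each peak in 4 columns and no score, height or p-value, and each library had its own list, per the labels. Calling peaks per library makes the presence of a peak depend on the depth of that library, which is unknown, so a deeper library can gain weak peaks that a shallower one lacks. Coordinates are printed counted from 1.

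Groups and replicate numbers were taken from the labels. Peaks of the 6 lists that overlapped by at least 1 bp were merged into 75738 consensus regions, and a library counted as open at a region where it had a peak in it. A region was specific to one population against another when both libraries of the first and neither of the second had a peak. Its background was the same count with 1 library of each population on either side. Similarity was the Jaccard index by bp, with exact permutation tests over the 15 ways to pair the libraries (one-sided) and over the 6 ways to split the IFE and HF libraries (two-sided). Intervals on shares are exact binomial at the 95% level.

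Genes came from a RefSeq table of GRCm38.p6, the assembly behind mm10, which gives gene spans without strand. The plan had named the nearest transcription start site. Without strand, each region was instead given to the nearest of 21887 protein-coding gene spans within 50 kb, and promoter shares became shares within 1 kb of either gene end. This placed 62802 regions (82.9%) at 15509 genes. Exons, introns and UTRs were not used here. A planned motif test was not run because no genome sequence was used here, and checks by peak score gave way to checks by peak width because the lists hold no score.

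For 21 gene lists, the number of regions specific to one population minus that of the other, corrected for the genome-wide proportion, was compared with 10000 random lists of the same size, matched on regions per gene in 10 bins, a permutation of genes. The test was two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison and a threshold of 0.05. The lists covered touch dome, IFE basal and suprabasal, hair follicle, infundibulum, sebaceous gland and Merkel cell genes, Hedgehog, Wnt, Notch, BMP and TGF-beta, Hox, neurotrophin and axon guidance, and stress genes. Others held sort markers and markers of melanocytes, immune cells, fibroblasts, endothelial and mural cells and Schwann cells. Single genes with at least 5 group-specific regions were tested with an exact two-sided binomial test against the genome-wide proportion, with Benjamini-Hochberg adjustment. Both tests run across genes or regions, which are not replicates, so they describe these libraries. The named genes were, per comparison and direction, the 10 with the largest net number of specific regions, up to 4 members of each list with a net number of at least 1, and the sort markers. Genes named outside that rule, chosen after their values were seen, were Ptch1, Lhx2, Tyr, Kit and Atoh1. Chosen likewise were the counts of Mitf, Lgr5, Nfib, Cd200 and Tgm3 across all libraries, and the genes named from tests added later. The lists, tests, naming rule and the first group of settings below were fixed before the data were examined, apart from the use of gene spans, which followed from the annotation.

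The region builder was tested on simulated peaks against a base-by-base count, with 0 of 396 library states wrong. On simulated regions at 15509 genes, 5.25% (touch dome against IFE), 5.50% (touch dome against HF) and 5.00% (IFE against HF) of 400 unchanged lists had p under 0.05. Lists of 20 genes whose rate of regions specific to the second-named population was raised 3 times were found in 57.5%, 75.0% and 85.0% of 40 trials. A raised rate toward the first-named population was not simulated. The gene test called 0 unchanged genes, of 12, 193 and 449 that reached the minimum of 5 regions in the same 3 comparisons. Simulated regions were drawn independently of each other, so false calls from regions that cluster within a gene were not tested. When genes were given specific regions of the second-named population alone, it found 100% of 62, 2.50% of 200 and 7.00% of 200, so genes with few regions seldom passed in the comparisons with HF.

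Other settings were a peak cover of at least 50% of the region, merging within 100 bp, autosomes alone, gene windows of 10 and 100 kb, regions near gene ends alone, each gene counted once, a minimum of 3 regions, leaving out each library, and a replicate block. Added after the data were seen were equal numbers of the widest peaks (50153 per library), the wider 50% of peaks, more random lists, lists without their leading gene or Tnc, a gene test against all consensus regions, and 20 draws each of random and width-matched thinning of touch dome replicate 2 to the peak number of replicate 1. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.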

Results

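Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts and tags open DNA, in 3 epidermal cell populations of mouse back skin. The mice carried a tamoxifen-inducible Cre under control of Tnc, the gene of the matrix protein tenascin-C, together with a tdTomato reporter. Touch domes are small patches of keratinocytes around hair follicles that hold the mechanosensory Merkel cells. Touch dome cells were sorted as EPCAM, SCA1, α6-integrin and tdTomato positive. Interfollicular epidermis (IFE) cells passed the same gate without tdTomato, and hair follicle (HF) cells were positive for EPCAM and α6-integrin but negative for SCA1 and tdTomato. Each population had 2 libraries of 50000 sorted cells from mice aged 60 days, and the data analysed were 6 peak lists. Nothing in the labels says whether the 2 libraries of a population came from separate animals, so the spread between them may be technical.

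Peak number was 50153 and 59250 in the touch dome libraries, 52219 and 51124 in IFE, and 54844 and 57131 in HF. Means were 54702 ± 6433 (SD, n = 2), 51672 ± 774 (SD, n = 2) and 55988 ± 1617 (SD, n = 2), so the groups differed by less than the spread between the touch dome replicates. The lists gave no read counts or peak heights, so sequencing depth is unknown and a missing peak means only that none was called. Peaks within 1 kb of the end of a protein-coding gene made up 22.3% ± 2.08 of touch dome, 23.5% ± 0.0817 of IFE and 21.8% ± 0.658 of HF peaks (SD, n = 2). Peaks elsewhere inside gene spans made up 39.0% ± 0.740, 38.7% ± 0.142 and 39.1% ± 0.242 (SD, n = 2). Overlapping peaks of the 6 lists merged into 75738 consensus regions with a median width of 953 bp, of which 34250 (45.2%) had a peak in all 6 libraries.

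The touch dome peak sets lay between those of IFE and HF and nearer to IFE. By the Jaccard index, the shared length of 2 peak sets over their joint length, touch dome and IFE libraries scored 0.716 ± 0.00635 (SD over 4 library pairs). Touch dome and HF libraries scored 0.610 ± 0.0237, and IFE and HF libraries 0.558 ± 0.0144 (SD over 4 library pairs each). Replicates scored 0.801 in IFE, 0.781 in HF and 0.723 in touch dome, and the last value hardly exceeded the highest touch dome and IFE pair at 0.721. Mean similarity within groups exceeded that between groups by 0.141, the largest of the 15 ways to pair the libraries (next 0.104). The one-sided exact permutation p was 0.0667, the smallest this design allows. Touch dome similarity to IFE exceeded that to HF by 0.106, with a two-sided exact permutation p of 0.333, again the smallest possible.

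**Figure D1:**
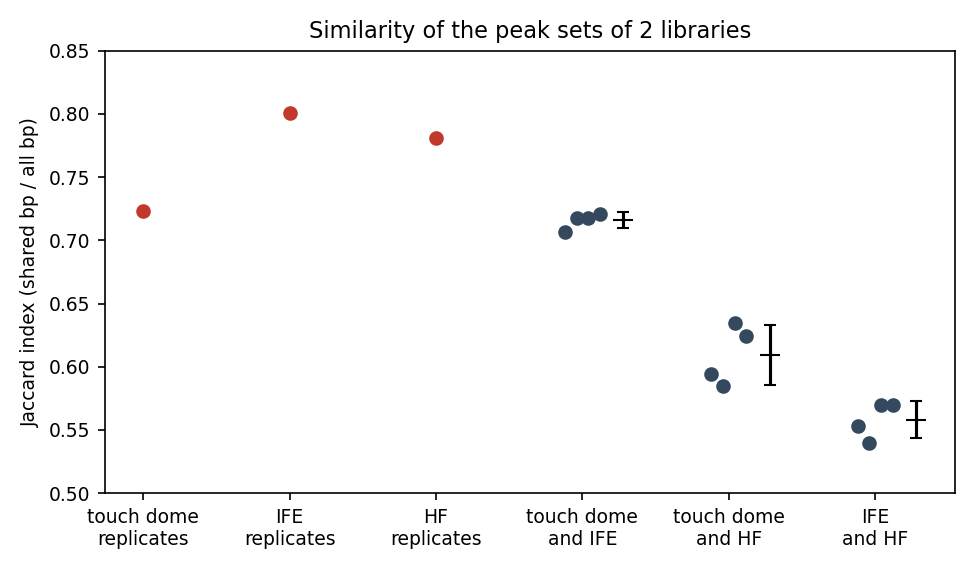
Jaccard index (vertical axis, shared bp over joint bp, starting at 0.5) of each pair of libraries, by the groups they come from. Each point is 1 library pair, and bars beside the points give the mean and SD over 4 pairs, which share libraries; all 4 touch dome and IFE pairs lie above the 4 touch dome and HF pairs.

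The comparison of touch dome with IFE asked what separates tdTomato-positive cells from other SCA1-positive basal cells. Touch dome cells had open regions at known touch dome genes that were closed in IFE, most of them also open in HF. Tnc itself, on chromosome 4 from 63959785 to 64047015 (mm10), had 6 regions open in both touch dome libraries and neither IFE library, and none the other way. All 17 consensus regions assigned to Tnc had a peak in both touch dome libraries, against 11 in each IFE library. Cadm1, a cell adhesion gene, had 7 touch dome regions and no IFE region, and Hhip, a Hedgehog antagonist, had 2 and none. Ptch1, a Hedgehog receptor gene, had 1 and none.

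Across the genome, 4096 regions were open in both touch dome libraries and closed in both IFE libraries, and 1360 showed the reverse. Regrouping the same libraries with 1 of each population on either side gave totals of 1522 and 1173 (crossed totals). Their sides held 1209 and 1096 regions where touch dome replicate 2, the library with the most peaks, was open, and 313 and 77 where it was closed. With equal numbers of the widest peaks, chosen after the data were seen, the counts were 3544 touch dome and 2278 IFE regions. The excess of touch dome regions was absent without touch dome replicate 2, with 4830 touch dome and 5071 IFE regions. Without touch dome replicate 1 the counts were 9421 and 1800. Without IFE replicate 1 they were 5254 and 2679, and without IFE replicate 2 they were 4917 and 3654. As merged over all 6 libraries, touch dome regions were wider (median 952 bp) than IFE regions (528 bp). Touch dome peaks themselves were not consistently wider, with medians of 862 and 912 bp against 936 and 896 bp in IFE. Of the touch dome and IFE regions, 3.34% and 5.88% lay within 1 kb of a gene end.

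Of 21 gene lists fixed beforehand, the touch dome keratinocyte list passed the random-list test, a permutation of genes and not of libraries. It held 19 touch dome and 0 IFE regions, where 71.1% of all such regions near genes were touch dome regions (excess of 10.8 net regions, adjusted permutation p = 0.00840). Of its 12 genes, 7 had more touch dome regions and 5 were even. Of the 19 touch dome regions, 16 were also open in both HF libraries, including 6 of 7 at Cadm1 and 5 of 6 at Tnc. Most were therefore not particular to touch dome. Of all 4096 regions open in touch dome and closed in IFE, 74.3% were open in both HF libraries. Leaving out 1 library loosens the criterion for its group and adds regions by construction. The excess was 19.4 without touch dome replicate 2, 17.5 without IFE replicate 2 and 11.8 without IFE replicate 1. Tnc drove the reporter used for the sort, so the list is not independent of the gate, and without Tnc the excess was 7.39 (adjusted permutation p = 0.0735). It was 6.81 without Cadm1 (0.231), 8.74 without touch dome replicate 1 (0.167), 1.48 near gene ends alone (0.124) and 3.62 with the wider 50% of peaks (0.241). The melanocyte list came close with 9 regions against 0 (adjusted permutation p = 0.0504), from Mitf (5), the melanocyte lineage regulator, Oca2 (3) and Dct (1), while the other 6 of its 9 genes with regions were even. Its excess of 5.23 net regions became 8.65 without IFE replicate 2 (adjusted permutation p = 0.0168), 2.37 without Mitf (0.314), 4.12 without touch dome replicate 1 (0.238) and 2.26 within 10 kb (0.633). The pigment gene Tyr and the receptor gene Kit had no region in any library.

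Genes of the Hedgehog pathway had 15 touch dome regions and 1 IFE region (adjusted permutation p = 0.139), with 4 and 0 at Gli2, a pathway transcription factor, and 3 and 0 at the co-receptor gene Boc. Hair follicle stem cell and outer root sheath genes had 37 and 10 regions (adjusted permutation p = 0.597), including 3 and 0 at Lgr5, a stem cell receptor gene, and 4 and 0 at Runx1. Wnt pathway genes had 26 and 4 (adjusted permutation p = 0.444), among them 6 and 0 at Ror2. IFE basal genes stood at 7 and 7 (adjusted permutation p = 0.444) and suprabasal genes at 4 and 2 (adjusted permutation p = 0.909). Without touch dome replicate 1 the IFE basal list passed toward IFE (adjusted permutation p = 0.0399). Merkel cell genes had 4 and 1 (adjusted permutation p = 0.909), with Piezo2, the touch channel gene, at 2 and 0. Atoh1, the Merkel cell master regulator, had a single region, with a peak in touch dome replicate 2 and IFE replicate 1. Counts were 21 and 9 for neurotrophin and axon guidance genes, 16 and 6 for the BMP and TGF-beta pathway, 7 and 2 for Hox genes, and 4 and 0 for the Notch pathway. They were 4 and 1 for hair follicle matrix and inner root sheath genes and for sebaceous gland genes, and 1 and 1 for infundibulum and junctional zone genes.

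Markers of other cell types, which the gate for EPCAM and α6-integrin selects against, gave 8 and 1 regions for fibroblasts, 4 and 3 for endothelial and mural cells, 2 and 0 for immune cells and 0 and 2 for Schwann cells. Immediate early and stress genes had 2 and 1. Among the sort markers, with 6 and 1 regions in all, Tnc held the 6 touch dome regions and Ly6a, which encodes SCA1, the IFE region. Epcam and Itga6 (α6-integrin) had none in either direction. None of the lists in this and the preceding paragraph passed (adjusted permutation p from 0.139 to 0.991).

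Among single genes, those with the most touch dome regions were Atp8a2, a phospholipid flippase gene (9 and 0, adjusted exact p = 0.527), and Dennd1a (8 and 0). Anks1b, App, Dpyd, Hmcn1, Ralgps1, Samd5 and Sdk1 had 7 and 0 each. The IFE direction was led by Slc16a10 and Sox6 (0 and 4 each) and the cadherin gene Cdh4 (1 and 5). With the exact binomial test, 0 of 62 genes passed after Benjamini-Hochberg adjustment, and 0 toward touch dome and 1 toward IFE did at an unadjusted p under 0.05. With 71.1% of regions on the touch dome side, even 9 against 0 gave an unadjusted exact p of 0.0674. An exact binomial test of touch dome regions among all consensus regions of a gene, chosen after the data were seen, called 17 genes toward touch dome, Tnc among them (6 of 17 regions, adjusted p = 0.0193), and 1 toward IFE.

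**Figure D2:**
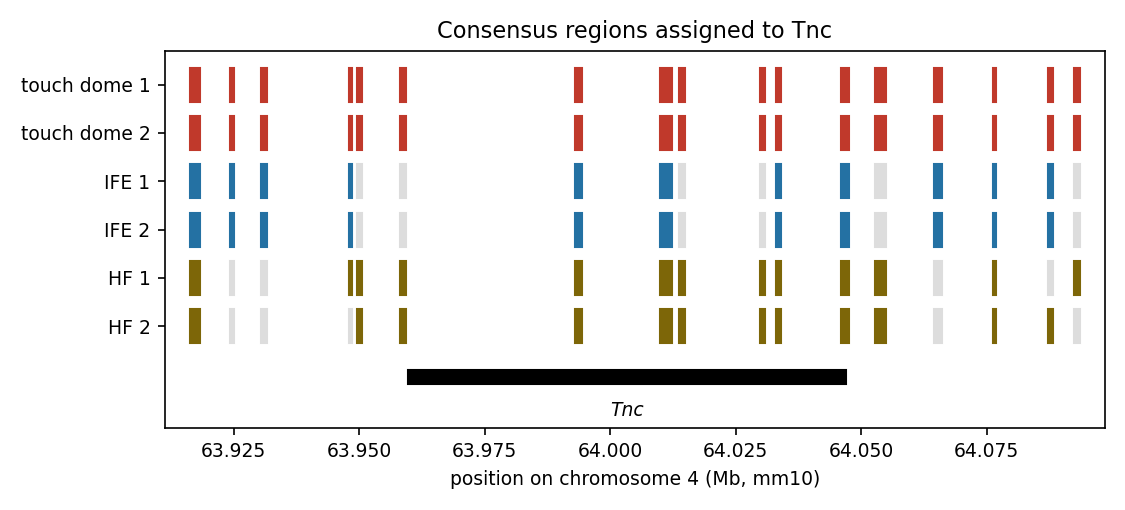
Consensus regions assigned to Tnc by position on chromosome 4 (horizontal axis, Mb, mm10), 1 row per library, coloured where the library had a peak and grey where it had none; the black bar is the gene span. The touch dome rows are coloured at all 17 regions, while IFE lacks 6 of them and HF lacks 3 others in both libraries.

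Touch dome and HF differed at more regions, and the hair follicle stem cell genes stood on the HF side. Their list had 64 HF regions and 18 touch dome regions, with Bnc2 at 11 and 1, Nfib at 6 and 0 and Runx1 at 7 and 3, all encoding transcription factors. On the touch dome side were Rora, a nuclear receptor gene (11 touch dome and 0 HF regions), the ion exchanger gene Slc24a3 (13 and 2), and the epidermal transglutaminase gene Tgm3 (6 and 1). Ly6a had 2 touch dome regions and no HF region, one of them inside the gene span on chromosome 15 from 74995454 to 74997869. SCA1, which Ly6a encodes, was part of the gate that separated these populations, so this difference is not independent of the sort. Itga6 had 5 and 1.

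Genome-wide, 6363 regions were open in touch dome and closed in HF, and 6036 the reverse, against crossed totals of 1025 and 718. Without touch dome replicate 1 the counts were 10970 touch dome and 6381 HF regions, without touch dome replicate 2 they were 7328 and 11281, and without HF replicate 1 they were 7506 and 9832. The hair follicle stem cell and outer root sheath list passed the random-list test (excess -47.6 net regions, permutation p = 1.00e-04, the smallest that 10000 random lists allow, adjusted p = 0.00210). Of its 30 genes, 19 had more HF regions, 2 had more touch dome regions and 9 were even. The excess was -58.3 without touch dome replicate 1 and -72.6 without touch dome replicate 2. At regions within 1 kb of gene ends alone the list had an adjusted permutation p of 0.322. None of the other 20 lists passed. Hox genes had 0 touch dome and 8 HF regions (adjusted permutation p = 0.143). Endothelial and mural cell markers had 2 and 11 (adjusted permutation p = 0.203, 8 of the 11 at Erg). The sort markers had 10 and 1 (adjusted permutation p = 0.143) and include Ly6a and Tnc, which are not independent of the gate. Hedgehog pathway genes stood at 6 and 10, the touch dome list at 10 and 13, IFE basal genes at 18 and 17, melanocyte genes at 3 and 2 and Merkel cell genes at 8 and 5 (adjusted permutation p from 0.869 to 0.967). Hox genes passed without HF replicate 2 (adjusted permutation p = 0.00840) and sebaceous gland genes without HF replicate 1 (0.0210).

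Nedd9 (10 HF and 0 touch dome regions), Bnc2 (11 and 1) and Adgrl3, Erg and Pcdh7 (8 and 0 for each of the 3) had the most HF regions after subtraction. Cfap299 and Slc35f1 (9 touch dome and 0 HF regions each), Dlg2 (11 and 2) and Arhgef3 (9 and 1) followed Rora and Slc24a3 on the touch dome side. With the exact binomial test, 0 of 285 genes passed after adjustment (lowest adjusted p = 0.123), and 19 toward touch dome and 33 toward HF did at an unadjusted p under 0.05. Of the hair follicle stem cell list, 2 of the 7 genes tested passed when adjusted over the list alone and 0 when adjusted over all genes. Without touch dome replicate 2, 5 genes passed toward touch dome, and 3 passed toward HF without touch dome replicate 1. An exact binomial test of group-specific among all consensus regions, chosen after the data were seen, called 10 genes toward touch dome and 2 toward HF.

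IFE and HF, the sorted populations furthest apart, differed at 7721 regions open in IFE alone of the pair and 11149 open in HF alone of the pair, against crossed totals of 847 and 344. With equal numbers of the widest peaks, chosen after the data were seen, the counts were close, at 8775 IFE and 8955 HF regions. Hair follicle stem cell and outer root sheath genes had 125 HF and 23 IFE regions. They included Bnc2 (20 HF and 1 IFE), Nfib (11 and 0), Runx1 (10 and 0), Postn (8 and 0), Lgr5 (7 and 0) and Lhx2, a bulge stem cell regulator (5 and 0). Hox genes, which set positional identity, had 20 HF and 2 IFE regions, spread over genes with at most 3 each, such as Hoxd3 (3 and 0) and Hoxc13 (2 and 0). On the IFE side Slc24a3 had 18 IFE regions and 1 HF region, Itga6 had 7 and 1, Tgm3 6 and 1, and Grhl3, a barrier gene regulator, 4 and 0.

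Both lists passed the random-list test, the stem cell list with an excess of -78.7 net regions (adjusted permutation p = 0.00210) and the Hox list with -16.3 (adjusted p = 0.0105). In the stem cell list 23 of 30 genes had more HF regions and 2 more IFE regions, and in the Hox list 13 of 35 genes with regions had more HF regions and 1 more IFE regions. The Hox list did not pass without IFE replicate 1 (excess -14.4, adjusted permutation p = 0.0514), without HF replicate 1 (-14.0, 0.113), within 10 kb (-14.4, 0.0651) or with equal numbers of the widest peaks (-14.8, 0.0854), where most of its excess was kept. With the wider 50% of peaks the excess was -4.12 (0.414). Wnt pathway genes had 32 IFE and 83 HF regions, Hedgehog genes 8 and 30, the touch dome list 10 and 32 and melanocyte genes 1 and 12 (adjusted permutation p = 0.147 for each of the 4). The touch dome list passed toward HF near gene ends alone (adjusted permutation p = 0.0238). The melanocyte list passed toward HF with a 100 kb window (adjusted permutation p = 0.0245). IFE basal genes had 31 and 26 and suprabasal genes 23 and 18 (adjusted permutation p = 0.408 for both). Fibroblast markers had 5 and 16, endothelial and mural markers 6 and 13, and immune markers 3 and 5 (adjusted permutation p from 0.394 to 0.800).

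**Figure D3:**
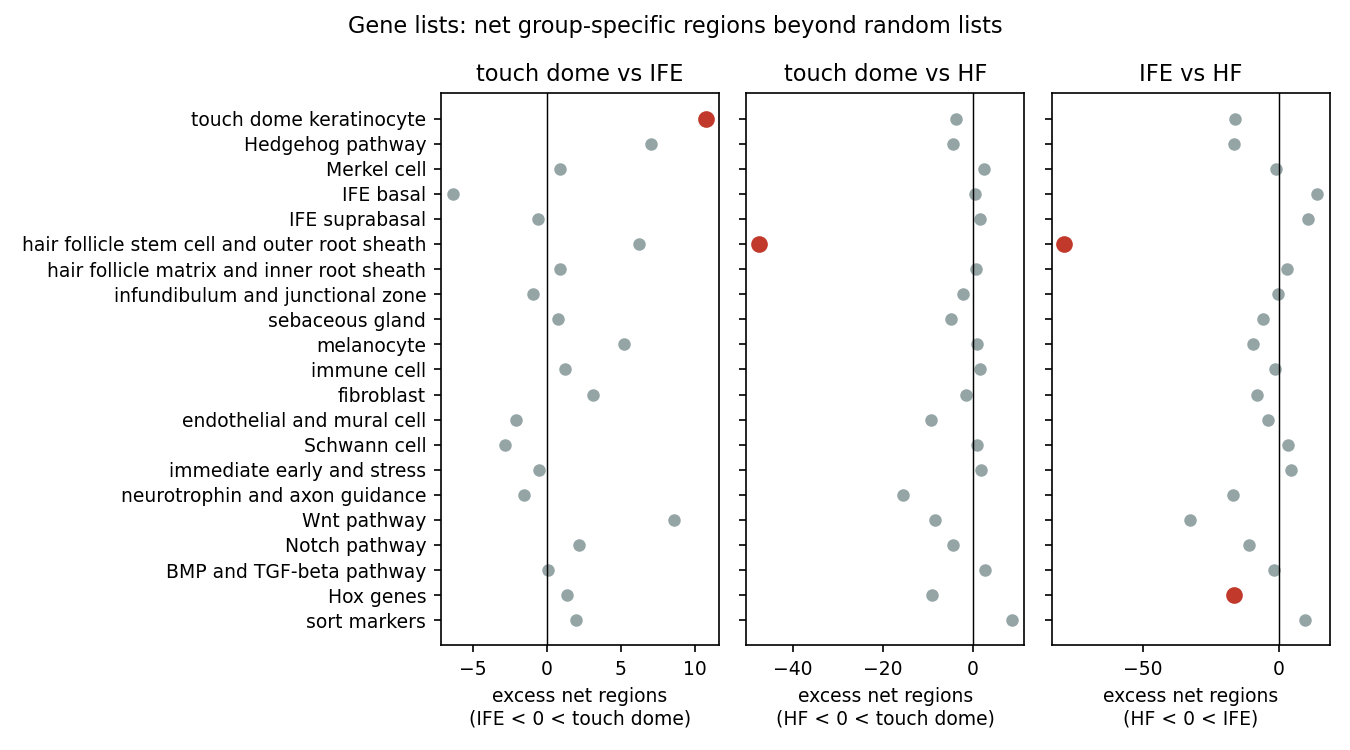
Net number of group-specific regions of each gene list beyond that of random lists (horizontal axis, regions), for the 3 comparisons. Red points passed at an adjusted p under 0.05: the touch dome list toward touch dome (10.8), the hair follicle stem cell list toward HF in both HF comparisons (-47.6 and -78.7), and Hox genes toward HF (-16.3).

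With the exact binomial test, 42 of 598 genes passed after Benjamini-Hochberg adjustment, 16 toward IFE and 26 toward HF. Slc24a3 (adjusted exact p = 0.00222) and Hmcn1, an extracellular matrix gene with 20 HF and 0 IFE regions (adjusted p = 0.00361), led. Toward HF they included Dpyd (16 and 0), App (15 and 0), Adgrl3, Dennd1a and Ext1 (14 and 0 each) and Atp8a2 (17 and 1). Toward IFE they included Dlg2 (16 IFE and 3 HF), Pibf1 (10 and 0) and Gna14, Il20ra, Mboat1, Nsf and Pla2g4e (8 and 0 each). Of the stem cell list, 5 of 11 genes tested passed when adjusted over the list alone and 3 when adjusted over all genes (Bnc2, Nfib and Runx1). Regions of a gene are not independent of each other, which this test does not take up, and the counts were 9 toward IFE and 5 toward HF without HF replicate 1, and 14 toward HF without IFE replicate 1. With a minimum of 3 regions per gene 1 gene passed in each direction, and with the wider 50% of peaks 0 did. Equal numbers of the widest peaks gave 3 genes toward IFE and 30 toward HF, and the test against all consensus regions 19 and 82.

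The title of the series concerns features of other epidermal lineages in touch dome keratinocytes, and the regions that separate IFE from HF address it. They were chosen by their IFE and HF peaks, though touch dome peaks helped set the boundaries of the merged regions. Touch dome cells had open regions of both kinds, more of those of IFE. Of the 7721 IFE regions, 67.4% (95% exact binomial interval 66.4 to 68.5) had a peak in touch dome replicate 1 and 84.6% (83.8 to 85.4) in replicate 2, a mean of 76.0% ± 12.1 (SD, n = 2). Of the 11149 HF regions, 28.9% (28.1 to 29.8) had a peak in replicate 1 and 51.3% (50.4 to 52.3) in replicate 2, a mean of 40.1% ± 15.8 (SD, n = 2). Both touch dome libraries had a peak at 4941 of the IFE regions and at 3045 of the HF regions. Neither had one at 925 and 5249. The intervals cover counting of regions only, and the difference between the shares was not tested.

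Of the 4096 regions open in touch dome and closed in IFE, 3045 (74.3%) were open in both HF libraries and 855 (20.9%) in neither. This share was no higher than among the 41259 regions open in touch dome and IFE (83.0%), but higher than among the 1360 open in IFE and closed in touch dome (17.9%). Of the 6363 regions open in touch dome and closed in HF, 4941 (77.7%) were open in both IFE libraries, against 89.0% of those open in touch dome and HF and 4.04% of those open in HF and closed in touch dome. Just 244 regions were open in both libraries of IFE and of HF and closed in touch dome. At Tnc, 5 of the 6 regions missing in IFE were open in both HF libraries, and the 3 regions missing in both HF libraries were open in both IFE libraries. Mitf (18 peaks in each HF library, 14 and 17 in touch dome, 10 and 11 in IFE, of 20 regions) and Lgr5 (12 and 14 in HF, 8 and 8 in touch dome, 4 and 4 in IFE, of 15) were intermediate. At Nfib touch dome overlapped IFE, with 30 and 37 regions in touch dome, 32 and 31 in IFE and 49 and 43 in HF, of 52. Cd200 did too, with 6 and 6, 5 and 7, and 10 and 10, of 11. At Tgm3 touch dome matched IFE, with 13 of 14 regions in each of these 4 libraries and 7 and 8 in HF. Mitf, Lgr5, Nfib, Cd200 and Tgm3 were chosen here after their counts were seen. Without IFE replicate 2 the touch dome mean at IFE regions was 61.9%.

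**Figure D4:**
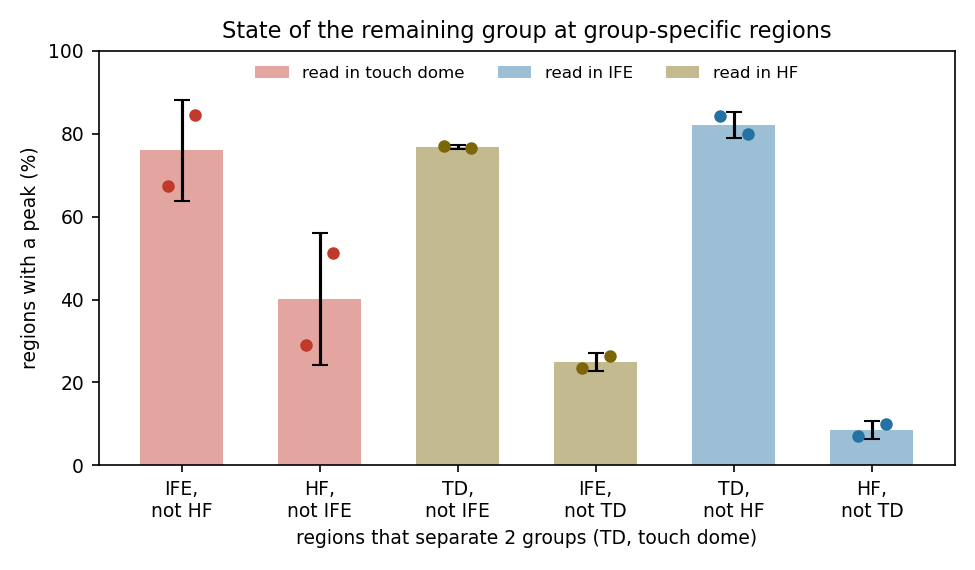
Percent of regions separating 2 of the populations (horizontal axis) that had a peak in the libraries of the remaining one (vertical axis). Points are libraries, bars the mean and error bars the SD (n = 2); touch dome had peaks at 76.0% of IFE regions and 40.1% of HF regions.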

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

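The settings by peak width, the larger number of random lists, the lists without a member and the test against all consensus regions were chosen after the data were seen. Touch dome remained nearer to IFE than to HF in all settings run, with a difference of 0.0723 (share of overlapping peaks) to 0.123. Keeping the wider 50% of peaks, which leaves fewer peaks by construction, gave 1646 touch dome and 616 IFE regions, 2866 touch dome and 2906 HF regions, and 3445 IFE and 5072 HF regions. It gave a within minus between similarity of 0.126 and 0 gene lists for touch dome against IFE. For IFE against HF, 0 genes passed in either direction, and the touch dome list passed toward HF in place of the Hox list. Equal numbers of the widest peaks gave 2278 IFE regions against touch dome, in place of 1360, with 3544 touch dome regions; for IFE against HF, 1 list and 3 genes toward IFE passed. Similarity within minus between groups by share of overlapping peaks was 0.107. The cause of these shifts beyond the smaller peak number was not tested.

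Leaving out 1 library loosens the criterion for its group, so counts rise by construction. Ranges were 4096 to 9421 (touch dome, not IFE), 1360 to 5071 (IFE, not touch dome), 6363 to 10970 (touch dome, not HF) and 6036 to 11281 (HF, not touch dome). The touch dome share of IFE regions ranged from 61.9% to 84.6%, and within minus between similarity from 0.110 to 0.187. Lists passing numbered 1 to 2 in each of the 3 comparisons. Without touch dome replicate 1 the list passing for touch dome against IFE was IFE basal, toward IFE, and not the touch dome list. Genes passing numbered 0 to 5 toward touch dome and 0 to 3 toward HF in touch dome against HF, and 9 to 16 toward IFE and 5 to 29 toward HF in IFE against HF.

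Lists passing for touch dome against IFE numbered 2 with autosomes alone, with a 100 kb window (melanocyte in both) and with each gene counted once (Hedgehog, adjusted permutation p = 0.0189), and 0 near gene ends. The melanocyte list had an adjusted permutation p of 0.0472 and 0.0199 in the first 2, 0.0168 without IFE replicate 2 and 0.0544 with 200000 random lists, and from 0.0504 to 1 in the others. An earlier draw of 10000 random lists had placed it just under the threshold. For touch dome against HF, 0 lists passed near gene ends. For IFE against HF, 1 list passed within 10 kb. Requiring 50% cover called 1 gene toward touch dome and 5 toward HF (touch dome against HF). For IFE against HF, genes toward IFE numbered 10 within 10 kb and 1 with a minimum of 3 regions, and genes toward HF 13 with merging within 100 bp, 12 within 10 kb, 17 within 100 kb and 1 with a minimum of 3. The test against all consensus regions called 17 genes toward touch dome and 1 toward IFE, 10 toward touch dome and 2 toward HF, and 82 toward HF against IFE. Peaks within 2 kb of gene ends made up 25.5% of touch dome, 26.8% of IFE and 24.8% of HF peaks. The cause of these shifts was not tested.

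With the replicate block, where libraries are compared with the same-numbered library alone, touch dome similarity to IFE exceeded that to HF by 0.104. Region counts do not change with the block, since they ask for both replicates. Differences between same-numbered replicates correlated at 0.0545, 0.00404 and 0.0591 across regions, under the 0.1 taken to call a pairing. Splits that kept same-numbered libraries together nevertheless held more regions than the other crossed splits (1522 against 1173, 1025 against 718 and 847 against 344), so whether same numbers mark a shared batch stays open. No list or gene changed the sign of its net number where it passed in the main or the changed setting. This number was corrected for the genome-wide proportion for lists but not for genes, so for genes its sign is not the tested direction. Where a list or gene passed in neither, the sign of that net number changed 129 times for lists and 26 times for named genes over all settings. Of the passing calls, 11 list values and 53 named gene values lost the threshold under some setting, and 10 and 19 gained it. Depth limits every absence: a missing peak can be a closed region or a shallow library. Checks by peak score and by motif were not run.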

Other observations

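All tests below were chosen after the results they concern were seen. Regions open in both touch dome libraries and none of the other 4 numbered 855, above the 600 regions that the most frequent pair of libraries from different populations held alone. They were spread thinly, with 5 at Cfap299, 4 each at Dock2, Kcnq3, Slc35f1 and Zfpm2, and 3 at Runx1, and 3.04% lay within 1 kb of a gene end, against 32.5% of the regions open in all 6 libraries. IFE had 925 such regions of its own, led by Cdh4 (5), and HF 5249, led by Bnc2 and Rad51b (11 each). Of these, 4.97% in IFE and 3.87% in HF lay within 1 kb of a gene end, so the low share was not particular to touch dome. Touch dome cells shared 9 HF regions closed in IFE at Atp8a2, 7 each at Dennd1a, Dpyd, Hmcn1 and Lrmda, and 6 each at Cadm1, Anks1b and the potassium channel gene Kcnma1. In the exact binomial test against all consensus regions of a gene, Tnfrsf11b, which encodes the decoy receptor osteoprotegerin (6 of 9 regions, adjusted p = 8.33e-04), Pdgfd (6 of 7, adjusted p = 2.11e-04) and Anks1b (7 of 11, adjusted p = 2.11e-04) led the touch dome regions closed in IFE.

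The share of HF regions closed in IFE that was open in both touch dome libraries is given here for lists chosen after their values were seen, and no difference between lists was tested. It was 16 of 32 for the touch dome list, of which Cadm1 gave 6 and Tnc 5. These 16 regions are among the 19 of that list open in touch dome and closed in IFE, given above. The share was 8 of 12 for melanocyte genes, of which Mitf gave 5, and 11 of 30 for Hedgehog genes, of which Boc and Gli2 gave 3 each. It was 30 of 125 for hair follicle stem cell genes and 2 of 21 for Notch genes, against 2058 of 8029 overall. Of IFE regions closed in HF, 28 of 32 at Wnt genes and 23 of 28 at BMP and TGF-beta genes were open in both touch dome libraries, but 15 of 31 at IFE basal genes, against 3964 of 6224 overall.

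Touch dome libraries had peaks at many HF regions closed in IFE. A larger number of called peaks is argued against for touch dome replicate 1. It had the fewest peaks of the 6 libraries (50153), yet a peak at 28.9% of these regions. Equal numbers of the widest peaks leave this library unchanged and trim the others. Its share of 35.3% in that setting is therefore no separate test. Replicate 2, trimmed from 59250 peaks, had a peak at 43.6% in that setting. There an IFE library had one at no more than 15.1% of the HF regions closed in the other IFE library. A steady admixture of HF cells with an average HF profile may also account for the pattern. The gate for SCA1 and tdTomato is meant to exclude such cells, since the HF cells were sorted as negative for both. How far it did so was not tested. Admixture predicts that presence in touch dome depends on peak width and not on the gene, yet presence correlated within genes by 0.0419 and 0.0472, above permutation (up to 0.0201). The same measure between the HF replicates was 0.0244 and 0.0730, so admixture and touch dome cells with open HF regions cannot be told apart here.

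Touch dome replicate 2 had peaks at more HF regions than replicate 1 (51.3% and 28.9%) and at more IFE regions (84.6% and 67.4%). A difference in peak number alone is argued against at HF regions by equal numbers of the widest peaks. Replicate 2 still exceeded replicate 1 there by 8.26 percentage points. The excess was 14.5 points after random thinning of the peaks of replicate 2 and 16.9 points after thinning matched on peak width. Random thinning drops strong and weak peaks alike, so its result follows from the shares and peak numbers already given. Thinning matched on width also drops peaks at random among those of like width, so neither imitates a shallower library. A candidate explanation, as a hypothesis, is a larger share of cells with an HF profile in replicate 2, which predicts a lower value than replicate 1 at IFE regions. The difference there was -3.26, 4.07 and 8.39 points in the same 3 settings, so its sign followed the way of thinning. This explanation and a more sensitive replicate 2 cannot be told apart here, since the lists hold no score to rank peaks by.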
